A study of Mus musculus with 7 samples.

How the data were processed

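Whole pancreatic islets were taken from 8-week-old C57BL/6J mice, 2 in the control group and 5 in the knockout (KO) group, and polyA-selected RNA was sequenced from each with a directional library kit, per the labels' protocols. Samples were grouped by their titles. The submitters' processing notes name HISAT2, DESeq2 and the genome build GRCm38, with no version, role or order. Counting software, strand setting and annotation release are not given in the sources used here.

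The authors deposited a table of all genes whose values are on a log2 scale. The values showed that the log2 scale is that of reads scaled to the depth of the library (RPM), since 2 to the power of a deposited value was a whole multiple of 1 step per library. Between 99.9% and 100.0% of values lay within 0.02 of a whole multiple, and a gene without reads was stored as 0.9 of a step. The step implies 23923000 to 43117300 reads per library, of which 54.6% to 57.0% fell in the listed genes. Among values of 1 to 20 steps, 63.9% to 66.7% were odd, so steps did not come mainly in pairs. Whether a step is an independent molecule stays open, and intervals and floors cover counting error only. A value of 3 reads, taken as the upper limit that a count of 0 allows, was 0.0696 to 0.125 RPM by library.

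A table of 136 selected genes also came from the authors, with the deposited mean log2 value of each group, a fold (ratio) of control over KO, and a corrected p-value. The authors' test and correction are not named in the file header. Every gene in it differed by at least 1.5-fold. The log2 differences are printed here with the sign turned to KO minus control.

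Of 34245 listed genes, 10613 had no reads in any library. Symbols turned into dates by a spreadsheet (26 genes) were restored by position against GENCODE M21 for 22 of them. Positions matched that annotation exactly for 92.7% of genes, and 46 genes shared a symbol with another.

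Genes entered the test when at least 2 libraries reached 10 reads at the median depth, which is 0.366 RPM, leaving 16212 genes. Values were taken as log2(RPM + 1), and limma 3.58.1 in R 4.3.3 fitted KO against control with an intensity trend. The tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A fold change on this scale understates the change of low genes. The design fixed before the data were examined assumed read counts and named limma-trend for normalised values, so limma was used. Means are given with the SD between libraries.

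A set of 31 gene lists, fixed before the data were examined, covered sterol synthesis, cholesterol efflux, ABC transporters, sphingolipids, fatty acids, beta cell genes, stress, inflammation, cell cycle, mitochondria, lysosomes, cytoskeleton and markers of other pancreatic cell types. Each was tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry.

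Genes named in the text follow a rule fixed before the data were examined. It takes Abca12, up to 8 rises and 8 falls past the threshold with at least 20 reads per library on average and no overlap of the groups, and for each list up to 2 members past the threshold or else the member with the smallest unadjusted p. Ins1, Ins2, Gcg, Sst, Prss2 and Xist are always given. Other genes named were chosen after their values were seen.

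The scripts were tested on simulated data for 2 control against 5 KO libraries over 16212 genes, in 10 runs. They recovered 57.3% of genes changed 1.5-fold, 81.4% of those changed 2-fold and 95.0% of those changed 4-fold, and 4.78% of calls were false. A list of 20 genes shifted 1.5-fold was found in 10 of 10 runs, and 2 of 300 unchanged lists were called. The simulated genes varied independently, while the estimated correlation between members was 0.87 for the acinar list. The list result therefore does not cover lists with correlated members. Each simulated gene took the spread typical of its level in the KO libraries, so differences between the 2 controls were not simulated. The rates of recovered genes and false calls may therefore not hold for these libraries.

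Alternatives covered scaling, filters, pseudocounts, voom on the recovered reads, an acinar score or sex as a covariate, the replicate number as a block, and leaving out each library. The acinar score was above both controls in each of the 5 KO libraries, so adjusting for it also takes out part of the KO difference. Leaving out a control leaves 1 mouse in that group, so the calls of those fits hold no spread between controls and carry little weight. The labels do not say whether the mice shared litters or days, so p-values measure the spread between these 7 libraries. Plots were drawn with matplotlib 3.10.9.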

Results

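Islets, the endocrine cell clusters of the pancreas, were profiled by RNA sequencing in 2 control and 5 KO mice at 8 weeks of age. In the KO group a floxed allele of Abca12, a lipid transporter of the ABC family, was deleted with Rip1-Cre, which acts in insulin-producing beta cells. Control 1 carried the Cre transgene with intact Abca12 and Control 2 carried Cre with 1 floxed allele, per the labels. Listed genes held 13336000 to 24590900 reads per library. Pearson correlations across genes between libraries ran from 0.980 to 0.994, and each of the 21 pairs differed by more than sampling noise (chi-square per degree of freedom of at least 8.42). KO 1 and KO 2 carry an f at the end of their column headers and the other 5 libraries an m. Xist, the RNA of the inactive X chromosome, stood at 385 and 368 RPM (reads scaled to sequencing depth) in KO 1 and KO 2 and at 0.362 to 0.533 in the others, so both female libraries lie in the KO group.

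Abca12 (chromosome 1, 71242276 to 71414910, minus strand, GRCm38) was listed at 0 reads in each of the 7 libraries, controls included. Its reads therefore check no label, and a level of up to 0.0696 to 0.125 RPM, by library, remains possible. Genes that every cell uses were detected, with 0 of 76 ribosomal protein genes at 0 throughout and at least 493 reads for each of 10 housekeeping genes. The deleted exon was not analysed separately here.

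Between KO and control islets, 7 genes rose and 3 fell. Gm15446, a predicted protein-coding gene on chromosome 5 (109923400 to 109943936), rose from 0.575 ± 0.429 (SD, n = 2) to 5.74 ± 0.635 (SD, n = 5) RPM, a log2 fold change of 2.12 (SE 0.17). Across all settings tried its log2 fold change ran from 0.95 to 3.60. Wdfy1, an endosomal protein with a lipid-binding FYVE domain, rose from 15.1 ± 4.21 to 28.1 ± 1.25 RPM (log2 fold change 0.88, SE 0.12). S100a10, the annexin A2 partner, went from 19.0 ± 1.68 to 35.3 ± 4.94 RPM. Gpnmb, a transmembrane glycoprotein of macrophages and pigment cells, fell from 8.41 ± 3.92 to 2.03 ± 0.276 RPM (log2 fold change -1.57, SE 0.21).

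Crispld2, a secreted protein, rose by 0.59 (SE 0.07) on the log2 scale, and C2cd4b, from a locus linked to diabetes risk, rose by 0.56 (SE 0.09). The matrix glycoprotein Thbs1 had a log2 fold change of -0.73 (SE 0.10), and Abat, which breaks down the transmitter GABA, one of -0.53 (SE 0.07). Gm26917 and CT010467.1, on chromosome 17, had log2 fold changes of 0.95 and 0.64. They lie beside Gm42418 and AY036118, and the group was handled here as transcripts of a copy of the ribosomal RNA repeat. Whether ribosomal RNA left in the libraries explains these calls was not tested. CT010467.1 (39848103 to 39848827, minus strand) overlaps Gm42418 (39846958 to 39848788, plus strand), and the strand setting of the authors' counting is not given, so this call is uncertain. Gm42418 and AY036118 did not pass (log2 fold changes 0.16 and 0.15, adjusted p = 0.919 and 0.922 by limma). In all 10 genes the 5 KO libraries lay on 1 side of both controls.

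**Figure D1:**
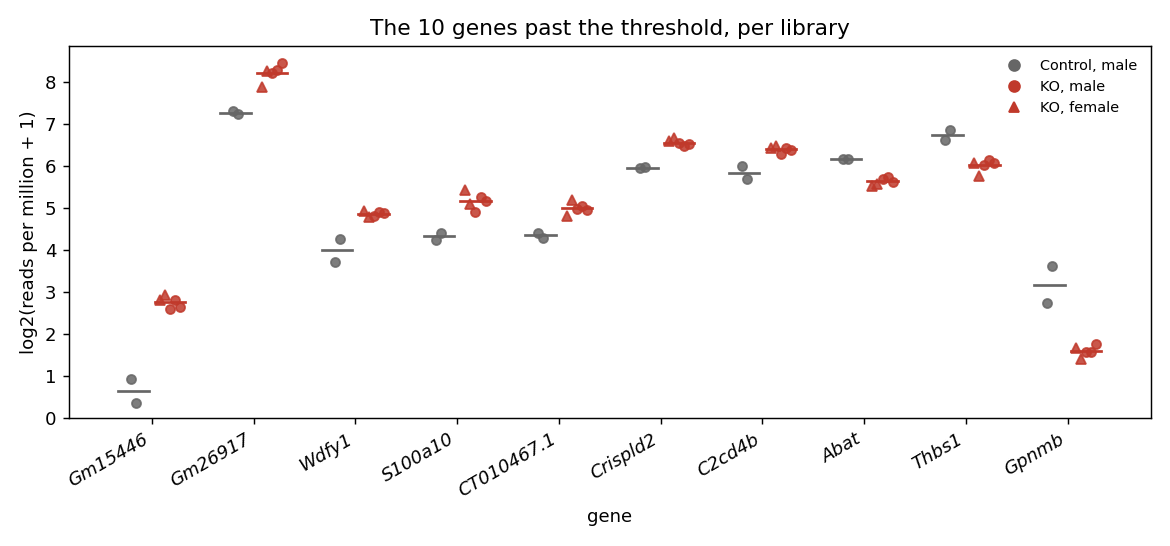
Log2(RPM + 1) of the 10 genes past the threshold in each library, with controls in grey, KO in red, female libraries as triangles and lines at group means. The 5 KO libraries lie apart from both controls for each gene, with Gm15446 at a log2 fold change of 2.12 and Gpnmb at -1.57.

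By limma the adjusted p was 0.00051 for Gm15446, 0.0131 for Crispld2, 0.0219 for Gm26917, 0.0228 for Gpnmb, 0.0261 for Wdfy1, Thbs1, Abat and S100a10, 0.0423 for CT010467.1 and 0.0433 for C2cd4b. At an unadjusted p under 0.05 there were 1749 genes, against 810.6 by chance and at most 1239 in the other splits of the libraries into 2 and 5, and the groups did not overlap for 15.2% of genes, against 9.52% by chance. The count of 10 moved to 3 without KO 3, 2 without KO 4 and 1 without a filter. It was 3 with sex and 2 with the acinar score as a covariate. It was 19 or 20 under other scalings, 42 with robust empirical Bayes, and 47 (41 higher and 6 lower) without KO 2 and KO 3. The last 2 settings were chosen after seeing the data. Leaving out a control sets 1 mouse against 5, so sizes alone are given for it in this section. With 1 library left out, controls included, the log2 fold change ran from 0.61 to 1.15 for Wdfy1 and from -2.01 to -1.14 for Gpnmb.

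Acinar transcripts were far more abundant in KO islets. Of 31 measured acinar markers, the digestive enzyme genes of the exocrine pancreas, 31 were higher on average in KO, 0 passed over all genes and 27 passed adjusted over the list alone. Their median log2 fold change was 2.67. Reg1, a secreted acinar protein, stood at 7.34 ± 1.44 (n = 2) and 80.7 ± 64.2 (n = 5) RPM, and the trypsinogen gene Prss2 at 51.4 ± 25.01 and 434 ± 350. Acinar genes took 0.190% and 0.104% of gene reads in Control 1 and Control 2, and 0.667%, 2.25%, 2.36%, 0.381% and 0.445% in KO 1 to KO 5. The list rose by camera (adjusted p = 8.44e-34; adjusted p = 0.494 with an estimated correlation). Without KO 2 and KO 3, chosen after seeing the data, the median was 1.75 and 24 members passed over all genes.

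Duct cell markers rose as a list (14 tested, median 0.18, adjusted p = 0.00812; adjusted p = 0.494 with an estimated correlation), and 3 members passed adjusted over the list alone. The keratin gene Krt8 stood at 214 ± 17.7 and 331 ± 35.9 RPM (adjusted p = 0.0539 by limma). The duct median was 0.07 without KO 1, 0.09 without Control 1, 0.10 without KO 4 and 0.28 without Control 2. The mean of the list was above both controls in each of the 5 KO libraries. The median shift from the control mean was 0.55, 0.34 and 0.20 in KO 1, KO 4 and KO 5, but -0.13 and -0.11 in KO 2 and KO 3.

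Markers of the other hormone cells were also higher. Delta and PP cell markers rose as a list (7 tested, median 0.55, adjusted p = 0.000182; adjusted p = 0.494 with an estimated correlation), with 5 members past adjusted over the list alone. Peptide YY (Pyy) stood at 393 ± 64.7 and 565 ± 49.1 RPM and somatostatin (Sst) at 608 ± 38.1 and 922 ± 266. Sst ran from 1013 to 1255 in KO 1 to KO 3, but was 659 and 639 in KO 4 and KO 5, beside 635 in Control 2. Alpha cell markers rose as a list (11 tested, median 0.37, adjusted p = 0.000658; adjusted p = 0.579 with an estimated correlation). Glucagon (Gcg) stood at 2875 ± 77.2 and 4308 ± 1861 and Higd1a at 2.21 ± 0.163 and 3.79 ± 0.683. In KO 5 Gcg stood at 2213, below both controls (2820 and 2930). Without Control 2 the alpha cell median was 0.27 and the delta and PP cell median 0.36. With the acinar score as a covariate the calls of both lists were lost, with medians of 0.14 and 0.38. That score was above both controls in each of the 5 KO libraries, so this fit also takes out part of the KO difference.

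Beta cell identity genes did not pass as a list. Of 26 tested, 13 were higher and 13 lower, the median was 0.01 and the adjusted p was 0.991. Insulin genes took 10.04% and 11.7% of gene reads in the controls and 8.31%, 9.32%, 10.05%, 10.3% and 12.6% in KO 1 to KO 5, with Ins1 at 22851 ± 2060 and 21001 ± 3989 RPM and Ins2 at 37144 ± 3624 and 35518 ± 5451. Ucn3, a peptide of mature beta cells, stood at 62.0 ± 0.000942 and 45.1 ± 5.87 (adjusted p = 0.132 by limma), and was below both controls in 5 of 5 KO libraries. Insulin exocytosis genes (29 tested, median -0.04, adjusted p = 0.910), genes repressed in mature beta cells (22 tested, median 0.06, adjusted p = 0.991) and genes of dedifferentiation (9 tested, median 0.10, adjusted p = 0.262) did not pass by camera, nor did prolactin response genes (11 tested, median 0.00, adjusted p = 0.991). By fry for change in either direction insulin exocytosis (adjusted p = 0.0184) and prolactin response genes (adjusted p = 0.0238) passed. The calcium channel gene Cacna1d of the exocytosis list stood at 72.7 ± 4.36 and 61.0 ± 3.83, Pdgfra of the repressed genes at 1.31 ± 1.14 and 0.175 ± 0.0993, Aldh1a3 of the dedifferentiation list at 2.90 ± 1.74 and 0.997 ± 0.337, and Gbp8 of the prolactin list at 24.6 ± 1.22 and 18.3 ± 2.20 RPM. Adjusted over their list alone, Ucn3, Aldh1a3, Pdgfra, Arhgdib and Gbp8 passed as lower in KO and Rbp4 and Tph1 as higher. Rbp4 is also in the delta and PP cell list, which rose. Without Control 2 the log2 fold change went from -0.88 to -0.36 for Pdgfra, which is also a stellate marker, and from -0.91 to -0.44 for Aldh1a3. Arhgdib stood at 2.17 RPM in Control 1 and 6.87 in Control 2.

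Transcripts of supporting cells were lower in KO islets. Stellate cell and fibroblast markers fell as a list (16 tested, 15 of them lower, median -0.79, adjusted p = 1.92e-09; adjusted p = 0.494 with an estimated correlation), with 7 past adjusted over the list alone. The collagen gene Col6a3 stood at 16.9 ± 9.80 and 6.77 ± 0.325 RPM. Endothelial markers fell as a list (15 tested, 15 lower, median -0.42, adjusted p = 7.02e-09; adjusted p = 0.494 with an estimated correlation), with 10 past adjusted over the list alone. The VEGF receptor gene Kdr stood at 32.4 ± 0.696 and 21.9 ± 3.89. Lymphocyte markers fell as a list (5 tested, median -0.90, adjusted p = 0.00107; adjusted p = 0.546 with an estimated correlation), with Ptprc, which encodes CD45, at 4.98 ± 4.21 and 1.83 ± 0.595.

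Control 2 decided much of this group. Without it the stellate median was -0.12, the lymphocyte median 0.08 and the endothelial median -0.27. Without Control 1 these medians were -1.44, -1.69 and -0.58.

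**Figure D2:**
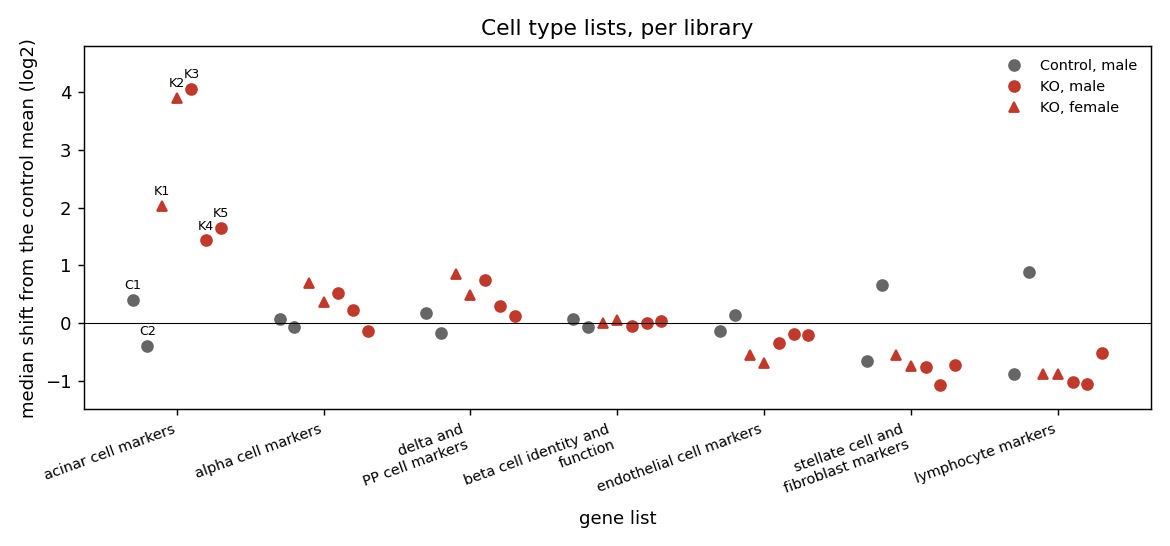
Median shift of each list's members from the mean of the controls (log2, y axis) for 7 cell type lists (x axis), with 1 point per library, controls in grey (C1, C2), KO in red (K1 to K5) and female libraries as triangles. Acinar shifts in KO run from 1.43 to 4.06, and in the stellate and lymphocyte lists Control 1 lies beside the KO libraries.

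Stress-related lists moved by small amounts. Unfolded protein response genes rose as a list (24 tested, 20 higher, median 0.12, adjusted p = 0.00038; adjusted p = 0.546 with an estimated correlation), while Sesn2, a member induced by amino acid and redox stress, stood lower in KO at 75.4 ± 2.34 and 62.7 ± 3.08. Immediate early genes rose as a list (20 tested, 17 higher, median 0.18, adjusted p = 0.000302; adjusted p = 0.494 with an estimated correlation), with the nuclear receptor gene Nr4a1 at 21.7 ± 10.2 and 33.6 ± 3.22 (28.9 in Control 1 and 14.5 in Control 2). Oxidative phosphorylation genes rose as a list (31 tested, 25 higher, median 0.07, adjusted p = 0.00545; adjusted p = 0.743 with an estimated correlation), with the complex III gene Uqcrc1 at 72.0 ± 0.654 and 80.2 ± 3.76. In these 3 lists 0 members passed, over all genes or adjusted over the list alone. By fry for change in either direction unfolded protein response genes passed (adjusted p = 0.0369). Without Control 2 their median was 0.02, and with the acinar score as a covariate their camera call was lost at a median of 0.09. Without Control 2 the immediate early median was 0.10. Without KO 5 the oxidative phosphorylation call was lost, with a median of 0.03.

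Lipid genes, the closest to the function of Abca12, showed no list past the threshold for a shift in 1 direction. Sterol synthesis and uptake (24 tested, median -0.04, adjusted p = 0.695), cholesterol efflux and LXR targets (15 tested, median -0.05, adjusted p = 0.677), other ABC lipid transporters (12 tested, median -0.05, adjusted p = 0.249), sphingolipid metabolism (26 tested, median -0.02, adjusted p = 0.551) and fatty acid synthesis (18 tested, median -0.06, adjusted p = 0.499) did not pass by camera. By fry for change in either direction the other ABC lipid transporters passed with the lowest adjusted p of the 31 lists (0.00330). Of the 12 members, 4 were lower and 1 higher in KO with no overlap of the groups, which held for 15.2% of all genes tested. The fry call was lost with the acinar score, with the replicate block, and without KO 2 and KO 3. In that last setting the median of the list was 0.003. Across the 5 lipid lists Insig1, a brake on sterol synthesis, stood at 61.0 ± 6.93 and 49.2 ± 5.16 RPM, Apoe at 54.2 ± 6.94 and 42.0 ± 7.71, the transporter gene Abca8b at 15.8 ± 0.290 and 10.5 ± 1.04, the glucosylceramide synthase gene Ugcg at 23.4 ± 0.118 and 18.6 ± 0.936, and Elovl5 at 72.6 ± 1.31 and 62.7 ± 3.49. Abca8b alone among these genes passed adjusted over its list.

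Other lists did not pass by camera either. Cell cycle genes had a median of -0.10 (22 tested, adjusted p = 0.0681) with Mki67 at 5.14 ± 2.66 and 2.36 ± 0.569. The cell cycle median was -0.26 without Control 1 and -0.00 without Control 2. Cytoskeleton genes had a median of 0.09 (23 tested, adjusted p = 0.0681) with gamma-actin (Actg1) at 264 ± 17.8 and 374 ± 28.6. Cytoskeleton genes passed by fry for change in either direction (adjusted p = 0.0184), and Actg1 passed adjusted over the list alone. The cytoskeleton median was 0.02 without Control 1 and 0.16 without Control 2. Lysosome and autophagy genes (26 tested) had a median of -0.04 and an adjusted p of 0.499, with the acid lipase gene Lipa at 17.3 ± 3.68 and 12.1 ± 1.69. The lysosome median was -0.08 without Control 1 and 0.01 without Control 2. Hypoxia and isolation stress genes (17 tested) had a median of -0.02 and an adjusted p of 0.695, with metallothionein Mt2 at 39.6 ± 17.0 and 78.7 ± 29.4. Inflammatory genes (16 tested) had a median of 0.01 and an adjusted p of 0.910, with Vcam1 at 4.29 ± 3.40 and 1.74 ± 0.335 (1.88 in Control 1 and 6.69 in Control 2). The inflammatory median was -0.18 without Control 1 and 0.13 without Control 2. Interferon response genes (21 tested) had a median of 0.06 and an adjusted p of 0.205, with Ifi27 at 19.9 ± 2.09 and 25.3 ± 4.23. The interferon median was 0.01 without Control 1 and 0.13 without Control 2. Macrophage markers (15 tested) had a median of -0.00 and an adjusted p of 0.969, with the mannose receptor gene Mrc1 at 1.02 ± 0.138 and 2.30 ± 0.610. Schwann cell and neuron markers (8 tested, median 0.11, adjusted p = 0.695), adipocyte markers (3 tested, median -0.09, adjusted p = 0.910), erythrocyte markers (2 tested, median -0.26, adjusted p = 0.131) and sex chromosome genes (5 tested, median -1.90, adjusted p = 0.260) did not pass, with Th at 5.15 ± 2.31 and 3.11 ± 0.460, Fabp4 at 6.56 ± 0.404 and 6.15 ± 1.05, Hba-a1 at 0.509 ± 0.166 and 0.226 ± 0.0593, and Uty at 21.9 ± 1.74 and 11.5 ± 10.5.

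**Figure D3:**
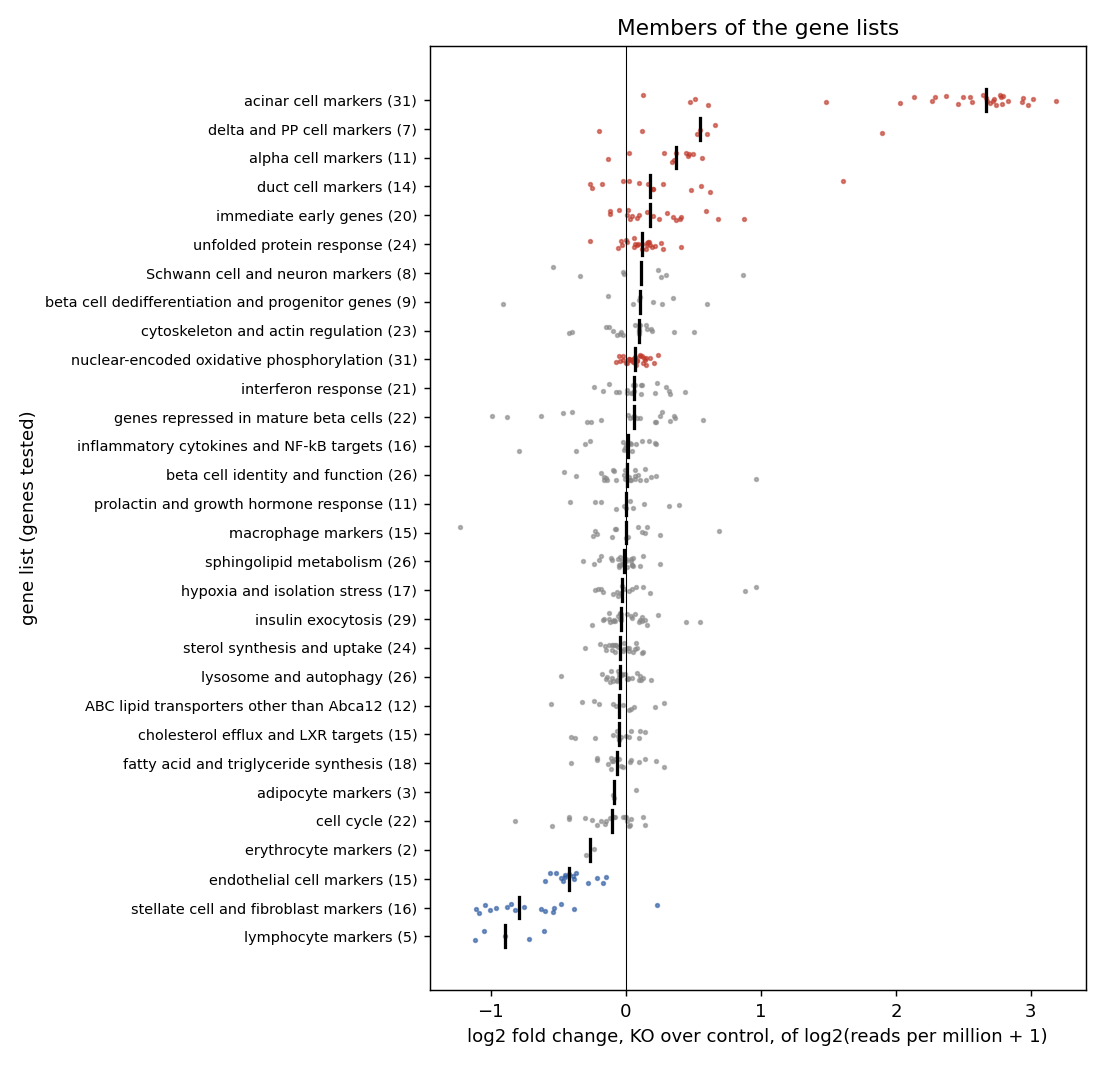
Log2 fold change of KO over control (x axis) for the members of 30 gene lists (y axis, genes tested in brackets), with a bar at each median, red for lists that rose and blue for lists that fell with the preset correlation. The acinar median lies at 2.67 and the lymphocyte median at -0.90.

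With the preset correlation 10 of 31 lists passed, 7 up and 3 down. With an estimated correlation 0 lists passed (2 at an unadjusted p under 0.05), and by fry 0 passed for a shift in 1 direction (5 at an unadjusted p under 0.05) and 5 for change in either direction. These 5 were the other ABC lipid transporters, insulin exocytosis, unfolded protein response, cytoskeleton and prolactin response genes, and 0 of them passed with the acinar score as a covariate. Fry does not compare a list with other genes. Median, mean and test differed in sign for 7 lists, none of them past the threshold by camera.

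The authors' deposited table names 136 genes, 63 higher and 73 lower in KO. Of these, 130 were tested here, 130 had the same direction, 8 passed over all genes and 129 passed adjusted over the list alone, which is not independent evidence since the table was chosen on these samples. In the authors' deposited table Gm15446 had a log2 difference of 3.55, and Gpnmb one of -1.98. The table holds 13 acinar and 5 stellate markers, along with Xist. Abat and C2cd4b passed here and are not in it. Their folds of KO over control here were 0.691 and 1.47, short of the 1.5-fold difference of every gene in that table.

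The control genotypes, with 1 mouse each, allow values only. Wdfy1 stood at 12.1 RPM in Control 1 and 18.1 in Control 2, Gpnmb at 5.64 and 11.2, and Gm15446 at 0.878 and 0.271. The controls differed by over 1 on the log2 scale for 1.03% of genes, against 0.0493% to 1.44% for the 10 pairs of KO libraries.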

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

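The test of sex for the acinar pattern was chosen only after the result was seen. The tests of acinar tissue, dilution, Control 2 and the Abca12 region were set after the largest fold changes and the authors' table had been looked at, but before their values were computed. In each of 4 cases 1 KO library stood far from the other 4, with its gap to the nearest taking most of the group's range. Gap over range was taken on the log2(RPM + 1) scale, while gene levels below are in RPM. Higd1a stood at 2.60 RPM in KO 5 and 3.83 to 4.25 in the other KO libraries (gap over range 0.780). Elovl5 stood at 56.8 in KO 2 and 63.2 to 65.9 in the others (0.727), and Apoe at 29.1 in KO 3 and 42.4 to 49.1 in the others (0.715). The mean of the lymphocyte markers was 1.66 in KO 5 and 1.19 to 1.29 in the other KO libraries (0.786). Chance alone would mark 3.9 of the 78 items examined, and 4 were marked.

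Acinar transcripts were higher in each of the 5 KO libraries, by 1.49 to 4.12 on the log2 scale over 25 abundant genes. Sex is argued against, since the acinar score of male KO 3 lay 3.53 above the higher control while the controls differed by 0.83. Acinar tissue carried along with the islets is a candidate explanation, since the acinar genes of a library shifted together. The SD over genes was 0.218 of the median shift, as the median over the KO libraries. That SD ran from 0.34 (KO 4) to 0.85 (KO 2) on the log2 scale, so the factor varied between genes. More exocrine tissue or acinar transcription in KO pancreas, which the genotype could bring, is untested and would look alike. Of the 31 list members tested, 13 are also in the authors' table and 26 reached 1 RPM in controls, with chymotrypsinogen Ctrb1 the highest at 170 in controls and 1522 in KO.

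Stellate, endothelial and lymphocyte transcripts were lower in KO libraries, with a median of -0.55 over 36 genes. Dilution by added acinar reads is argued against, since reads of the acinar list could lower other genes by no more than -0.03 on the log2 scale, from their shares of gene reads, while these genes lay -0.56 from the beta cell median. A Control 2 sample richer in these cells may account for part, as the median without Control 2 was -0.20, 0.370 of its size. The 3 lists differed in this. Without Control 2 the stellate median went from -0.79 to -0.12 and the lymphocyte median from -0.90 to 0.08. The endothelial median went from -0.42 to -0.27, so Control 2 carried less of that fall. With 2 controls a richer Control 2 cannot be told apart from a KO effect. An effect of the genotype stays open and untested.

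Wdfy1 lies 8.41 Mb from Abca12, and in the heterozygous control it stood 0.470 of the way from the Cre control to the KO mean. The same position ran from -0.769 to 0.183 for the other 9 called genes, so in 1 heterozygous mouse it decides nothing. Alleles that travel with the targeted locus could raise Wdfy1. Within 20 Mb of Abca12, 12 of 247 genes (4.86%), Wdfy1 itself included, had an unadjusted p under 0.01, against 3.50% elsewhere (one-sided Fisher's exact p = 0.164). With so few genes this cannot be told apart from an effect of the deletion, which stays open.

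Of the 21 splits of the 7 libraries into 2 and 5, 2, the real one included, gave at least as many genes past the threshold as the real 10, so chance cannot be excluded for that count. At an unadjusted p under 0.05 the real split was the highest of the 21, with 1749 genes against at most 1239. The highest other split, 27 genes, set KO 2 and KO 3 apart, the libraries with the most acinar reads, which points to a structure of the samples. Setting the females KO 1 and KO 2 apart gave 8, and the remaining 18 splits gave 0.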

How the results depend on the processing

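Alternatives chosen after seeing the data were TMM over all genes, deposited log2 values, pseudocounts of 0.03 and 0.5, voom without weights, robust empirical Bayes, males only, and leaving out KO 2 and KO 3. The 10 called genes kept their direction and an unadjusted p under 0.05 in all 25 other settings. Their calls were lost in 2 settings for Gm15446, 4 for Crispld2, 6 for Gm26917 and Wdfy1, 7 for Gpnmb and Thbs1, 9 for Abat, 10 for S100a10, 12 for CT010467.1 and 14 for C2cd4b.

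The count of 10 genes became 19 with median-of-ratios scaling, 20 with TMM outside acinar and hormone genes and 20 with TMM over all genes. It became 1 without a filter (Hoxa10, so 0 of the 10), 2 with the acinar score, 3 with sex, 47 without KO 2 and KO 3 and 42 with robust empirical Bayes. Leaving out 1 library gave 2 to 127, and males alone gave 13, with 8 of the 10 kept. The upper end of the range for leaving out 1 library came from the fit without Control 1. That fit leaves 1 control mouse, so its calls carry little weight. Leaving out 1 KO library gave 2 to 13. With the acinar score 6 lists passed, 5 of the 10 and cytoskeleton genes, and unfolded protein response, alpha, delta and PP, acinar and lymphocyte lists were lost. The 10 lists became 0 with an estimated correlation and 0 by fry, and 9 to 11 when 1 KO library was left out. With the acinar score, which is made from that list, the acinar median was 0.016 and the test turned, as it did for alpha cells (median 0.14). Without Control 2 the tests turned for lymphocyte markers (median 0.082) and genes repressed in mature beta cells (0.13), which stood at -1.69 and -0.16 without Control 1. Lists past the threshold only elsewhere included cytoskeleton genes in 9 settings and cell cycle genes in 3. Without Control 2 the log2 fold change was -0.36 for Mki67, -0.08 for Vcam1 and 0.21 for Nr4a1, against -1.27, -1.499 and 1.15 without Control 1. Except where construction shows it, the cause was not tested. By fry for change in either direction the call for the other ABC lipid transporters was lost in 3 of 24 settings (replicate block, acinar score, without KO 2 and KO 3), and the other 4 in 9 to 13. Abca12 stayed at 0 reads in all settings.

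The groups share numbers 1 and 2 in titles alone. Same-numbered libraries correlated at -0.10 and -0.24, though with 2 controls the deviations mirror each other, so this check is weak. The replicate block rested on KO 1 and KO 2, both female, against the 2 male controls, as no control shares the other numbers. In that fit 11 genes passed, 0 of them among the 10, and 12 lists passed. The genes included Xist and Uty and the lists the sex chromosome genes, so sex and KO cannot be separated there. DESeq2's Wald test was not run, since the deposited values are log2 RPM; recovered reads entered voom and the scaling factors. Values are scaled by library totals except in the scaling alternatives. Signs of results past the threshold in neither fit were not followed, apart from 6 named genes that changed sign with the acinar score, 2 with sex, 2 in males and 1 without Control 2. Depth limits low genes, with a floor of up to 0.125 RPM.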

Other observations

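The tests of tubulin genes and of the Gm15446 region were chosen only after the results were seen. Tubulins, the subunits of microtubules, were in no list as a group. Of 14 alpha, beta and gamma tubulin genes tested, 11 were higher in KO, and for 10 of them the 5 KO libraries lay above both controls, against 0 that passed over all genes. Under other settings Tuba1b passed with both TMM scalings, and Tubb4b, Tuba1b, Tuba1a and Tubb5 with robust empirical Bayes. Tubb4b stood at 111 ± 2.81 (SD, n = 2) and 153 ± 12.8 (SD, n = 5) RPM, Tuba1b at 52.5 ± 5.31 and 71.2 ± 3.36, Tuba1a at 106 ± 0.548 and 138 ± 8.78, and Tubb5 at 97.1 ± 3.95 and 129 ± 9.94. Tubg1 stood at 32.6 ± 0.494 and 32.6 ± 3.08.

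The tubulin median was 0.37 on the log2 scale, 0.38 under each of 3 other scalings, 0.34 to 0.40 when 1 library was left out, and 0.38 with sex or the acinar score as a covariate. By camera the p was 1.31e-11, and 0.00183 with an estimated correlation, both too small because the family was picked for its values. The median stood at percentile 100 of 10000 random lists matched on mean level, which carries no weight for a family so picked. The matched lists themselves had a median of -0.00 (95% of them within -0.08 to 0.08), so a shift of all abundant genes by this much is argued against. A change in tubulin transcripts with the genotype may be present, as a hypothesis found and tested on the same 7 libraries.

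Gm15446 has Zfp932 as a neighbour, which had a log2 fold change of 0.65 (SE 0.15, adjusted p = 0.132 by limma). Gm17655, 0.126 Mb away, had one of 0.39 (SE 0.16, adjusted p = 0.401 by limma). Alleles of that region which differ between the mice could raise these genes. Within 2 Mb, 2 of 54 genes had an unadjusted p under 0.01, 3.70% against 3.52% elsewhere (one-sided Fisher's exact p = 0.571). These were Zfp932 and Ttc28, which was lower in KO (log2 fold change -0.31). A share over 2 Mb cannot show a change confined to the nearest genes, so this explanation stays open.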
